A study of Arabidopsis thaliana with 8 samples.

How the data were processed

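Transcript levels were measured in rosette leaves of Arabidopsis thaliana Col-0 on 8 2-colour Agilent arrays in the 4x44K format. Per the labels, plants were 22 days old and grew at 23 °C with 16 h of light and 8 h of dark at a light intensity of 160 µE, and leaves were taken 2 h after treatment. In herbivore wounding (HW), larvae of the moth Spodoptera littoralis fed on the leaves. In mechanical damage (MD), a pattern wheel was used. The plants were wild type (WT) or PDKO3, a line that the labels describe as mutated in 3 plasmodesmata genes without naming them. Each labelling reaction started from 500 ng of total RNA. The series' design text states 3 biological replicates per condition, so the p-values measure the spread between biological replicates as the submitters define them, pooled over the 8 arrays. It also mentions technical replicates, and no array was marked as one in the labels used here.

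The arrays formed 3 sets, grouped by the titles and the channel labels. On 3 arrays WT after MD was labelled with Cy3 and WT after HW with Cy5. On 3 arrays PDKO3 after MD carried Cy3 and PDKO3 after HW Cy5. On 2 arrays WT after MD carried Cy3 and PDKO3 after MD Cy5. No dye swap was present, so a gene-specific dye effect stays in each ratio, and it cancels only in the difference between the PDKO3 and WT ratios. The arrays lay on 2 slides of 4 arrays each. Slide 1 held WT replicates 1 and 3, PDKO3 replicate 2 and replicate 1 of the comparison between genotypes, and slide 2 held the other arrays. Scans divided the arrays in the same way as slides. By the RNA numbers in the names under which the arrays were deposited, the arrays between genotypes appear to carry MD RNA that was also hybridised on the HW against MD arrays, which the labels do not state.

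Spot intensity and local background intensity were deposited by the authors as scanner output of Agilent Feature Extraction 9.5.1.1, before background correction, per the file headers. The scanner software's log10 ratio of Cy5 over Cy3, deposited in the same files, followed its own background, detrending and linear plus LOWESS dye normalisation, per the file headers. The deposited series table holds log2 ratios, and limma 3.4.4 was used per the submitters' processing notes, which do not give the step. Across bright probes the table's values had a slope between 0.963 and 0.972 on the scanner's log2 ratios, with Pearson's r across probes from 0.971 to 0.995. The scale and the direction of Cy5 over Cy3 were therefore taken as settled for the table. Its column medians were −0.00101, 0.00391 and 0.00543 for PDKO3 replicates 1 to 3, 0.00601, 0.00471 and 0.00317 for WT replicates 1 to 3, and 0.00669 and 0.00337 for replicates 1 and 2 between genotypes. Centring near 0 was visible, while the method of centring stayed unknown. The table had 4 missing values, all on PDKO3 replicate 1. It was used only as an alternative.

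From the intensities, background was corrected with normexp at an offset of 50, and each array was normalised by loess with control spots and outlier spots at weight 0. Values of outlier spots were then left out, 175 among the genes tested. Spots of a probe were averaged. Of 43603 probes, 37540 matched 1 locus in the annotation column of the files, 873 several and 5190 none, and only the first kind was used. A gene with several probes, as 7094 genes had, was represented by the probe with the highest mean intensity, and other probes of a named gene were compared with it by sign. Loci were given as AGI codes. Of 28479 loci, 28074 were found in the gene table of the TAIR10.1 assembly, which supplied symbols for 10424, and no coordinate was taken from it. Probe positions are those of the array files, on the genome release that the file headers call ath1. A gene was tested when its probe was well above background in at least 1 channel on at least 2 arrays, which kept 19425 genes and left out 9054 as dim.

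Precision is limited by the number of arrays. Probes well above background made up 57.9% to 61.9% of probes in Cy3 and 62.7% to 66.8% in Cy5. Between 20 and 189 spots per array were marked as outliers and 0 as saturated, and the slope of observed on expected spike-in ratios was 0.879 to 0.911. The log2 ratios correlated across genes with r of 0.461 to 0.615 between WT arrays, 0.538 to 0.750 between PDKO3 arrays, and 0.622 between the arrays comparing genotypes. Genes are not independent replicates in these correlations.

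Changed genes were called with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and files were read with data.table (version 1.17.8). The model had 1 mean per set over all 8 arrays, with 5 residual and 3.46 prior degrees of freedom, and the threshold was a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. As the sets shared this spread, p-values between genotypes rest mostly on the spread of the HW against MD arrays. Arrays that may carry the same MD RNA were treated as independent. The comparisons were HW against MD in WT, HW against MD in PDKO3, PDKO3 against WT after MD, the difference of the first pair, and their mean over 6 arrays. Errors are SE of the model. The between-genotype comparison tested 19423 genes, because 2 genes had no ratio on its arrays. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over lists, and again with an estimated correlation. With the estimated correlation, 0 of the 35 lists passed in any comparison (camera of limma, with 2, 1, 2, 3 and 2 lists at an unadjusted p under 0.05 in the order of the comparisons), so every list call rests on the preset value. Of 36 lists, 34 were fixed by AGI code and 2 by rule, and the meristem and dividing cell list had 1 measurable member, CYCB1;1, and was not tested. A gene below background in a whole group has only a bound.

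The named genes followed a rule. In each comparison these were the 10 largest rises and the 10 largest falls that passed, had the same sign on every array (for the difference between genotypes, no overlap of WT and PDKO3 arrays) and were well above background in the brighter group on all of its arrays. From each list up to 4 members with the smallest p were added, and the plasmodesmata located proteins and reference genes as groups. Of the genes the rule names, 1 is not reported here. The sets of arrays, tests, lists, this rule and most alternatives were chosen before the data were examined. The fits within each slide, the derived PDKO3 against WT contrast after HW and the clock sets were chosen after seeing the data.

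The alternatives were no background subtraction, an offset of 0, the scanner's log ratio, median centring, scaling between arrays, no filter and a filter on all 8 arrays, the mean of all probes, only the arrays of a comparison, leaving out each array, the replicate number or slide as a term, slide as a random block, the series table, a trended robust prior, array weights, separate channels and a 2-fold minimum. Under median centring the median of all genes moved to 0.40 in WT, 0.46 in PDKO3 and 0.55 between genotypes, against 0.02, 0.04 and 0.02 with loess, and changes under that setting are read relative to these shifts.

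The tests were tried on simulated data for 19425 genes with the spread of the real arrays. In each comparison 67 genes were changed by 1.5-fold and another 67 by 2-fold. Errors were independent between genes and arrays, so shared RNA was not simulated. Of genes changed 2-fold, the model recovered 97.0% in WT, 100% in PDKO3, 95.5% between genotypes and 91.0% for the difference, and of genes changed 1.5-fold 83.6%, 79.1%, 71.6% and 32.8%. False calls numbered 8, 8, 10 and 8. For the mean of both genotypes 98.5% were recovered at either size, with 15 false calls.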

Results

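Leaf transcripts were compared between herbivore wounding (HW, feeding by Spodoptera littoralis) and mechanical damage (MD, a pattern wheel) in wild type (WT) and in PDKO3 plants, and between the genotypes after MD. The design asked which transcripts respond to the herbivore beyond the damage itself, and whether that response differs in plants with mutated plasmodesmata genes. Plasmodesmata are the channels that join the cytoplasm of neighbouring plant cells. There were 3 arrays of WT HW against WT MD, 3 of PDKO3 HW against PDKO3 MD and 2 of PDKO3 MD against WT MD. No array carried RNA of undamaged plants. In HW against MD, a rise or fall means only higher or lower after HW than after MD. The opposite change after MD cannot be told apart from it. Values are log2 ratios with the SE of the model, and adjusted p-values are from limma. The number of arrays limits the precision.

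The labels do not name the 3 genes mutated in PDKO3, so no targeted transcript could be used to check them. Of the plasmodesmata located proteins (PDLP), membrane proteins of these channels, PDLP3 (AT2G33330, probe on chromosome 2 from 14130062 to 14130121) was 3.83-fold lower in PDKO3 than in WT after MD, at −1.94 ± 0.29 (n = 2, adjusted p = 0.00515), with −2.68 on slide 1 and −1.19 on slide 2. PDLP1 (AT5G43980) was lower at −0.61 ± 0.17 (adjusted p = 0.0471). Its value turned to 0.06 under median centring of the arrays, where the median of all genes was 0.55, and without replicate 1 or 2 between genotypes its call was lost at −0.71 and −0.52. That call also ended without PDKO3 replicate 2 or 3 or WT replicate 1 or 3, which set only the spread. PDLP2 stood at −0.44 ± 0.14 and did not pass (adjusted p = 0.0785). In the list of plasmodesmata located proteins, 2 of 7 members fell and 5 did not pass, with 3 lower when adjusted over the list alone. Its median was −0.29 by loess or with slide as a term, −0.10 within slide 1 and −0.38 within slide 2, with a camera adjusted p of 0.0393, against an adjusted p of 0.504 with an estimated correlation.

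In WT, the median of the salicylic acid pathway list was higher after HW than after MD, with 11 of 17 members past the threshold, and medians of the detoxification and heat shock lists were lower, with 7 of 10 and 11 of 16 lower. None of these lists passed with an estimated correlation. WRKY38 (AT5G22570, probe on chromosome 5 from 7495661 to 7495720), a transcription factor of salicylic acid responses, rose 6.08-fold, at 2.61 ± 0.31 (n = 3, adjusted p = 0.00311), with 2.69, 1.50 and 3.63 on the arrays. UGT74E2 (AT1G05680, probe on chromosome 1 from 1703230 to 1703289), a glucosyltransferase, fell 7.39-fold, at −2.89 ± 0.14 (adjusted p = 0.000181). The glutathione transferase GSTU24 (AT1G17170) fell 4.98-fold, at −2.31 ± 0.10 (adjusted p = 0.000107). The small heat shock protein gene AT1G53540 fell 7.79-fold, at −2.96 ± 0.42 (adjusted p = 0.00534).

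Altogether 2450 of 19425 genes, or 12.6%, differed between HW and MD in WT, 1340 higher and 1110 lower, and 131 and 102 of these by at least 2-fold. Other large rises were in NIA1 (AT1G77760), a nitrate reductase, at 2.22 ± 0.19, PCR1 (AT1G14880) at 2.46 ± 0.34 and BT2 (AT3G48360), a BTB and TAZ domain protein, at 2.06 ± 0.28. AT4G36850, a PQ-loop membrane protein, stood at 2.59 ± 0.27. Large falls also included the ferritin FER1 (AT5G01600) at −2.08 ± 0.25, the ribonuclease RNS1 (AT2G02990) at −1.82 ± 0.30 and the lipid transfer protein LTP3 (AT5G59320) at −1.81 ± 0.18. Among hormone and signalling genes, the transcription factors ERF1 (1.09 ± 0.14) and ERF2 (1.73 ± 0.16), the ethylene receptor ETR2 (0.82 ± 0.09) and the calmodulin-like TCH3 (1.19 ± 0.14) rose. CYP94B3 (−1.43 ± 0.23) and the sulfotransferase ST2A (−1.27 ± 0.19), which inactivate jasmonates, fell, as did the wax synthesis gene CER1 (−1.22 ± 0.14). These genes kept their calls without any one array. Of the 94 named genes that passed in WT, 44 did so, and 77 passed with slide as a term.

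**Figure D1:**
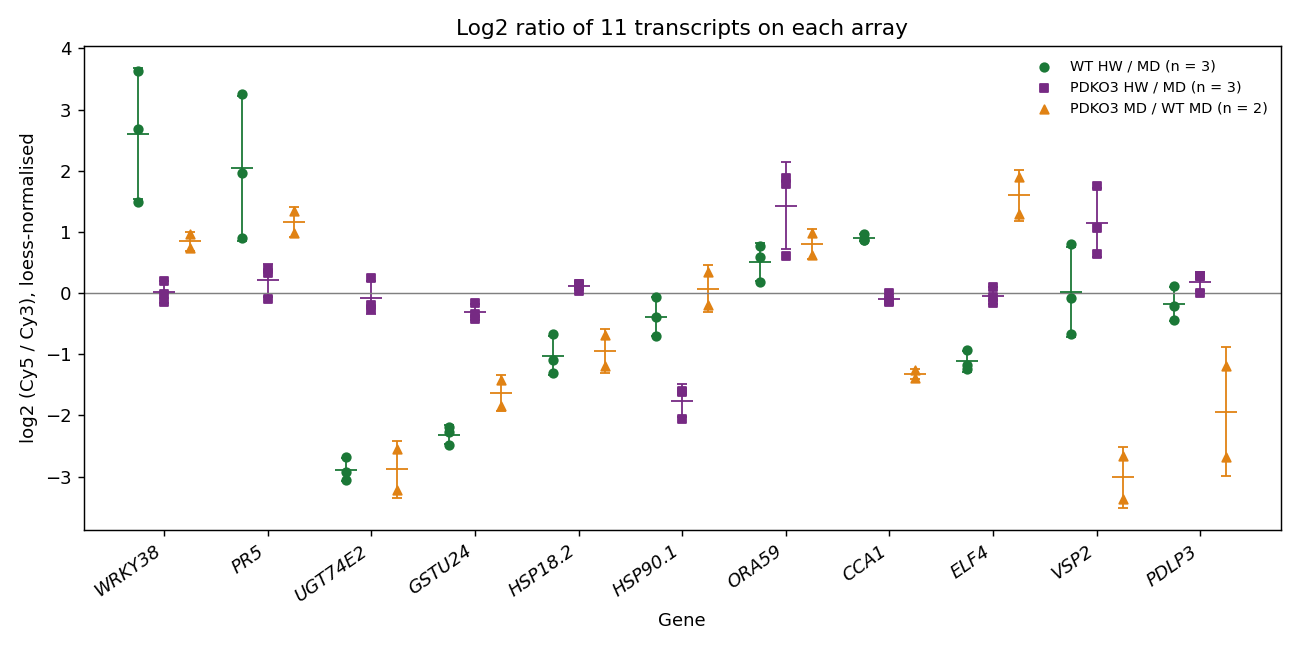
Log2 (Cy5 / Cy3) of 11 transcripts on each array, with a point per array, horizontal lines for the means and bars for the SD. WRKY38 lay between 1.50 and 3.63 on the 3 WT arrays, and UGT74E2 averaged −2.89 in WT HW against MD and −2.88 in PDKO3 MD against WT MD.

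Of the 17 measured members of the salicylic acid pathway list, 11 rose and 6 did not pass, with 12 higher when adjusted over the list alone. The members with the smallest p were WRKY62 (0.93 ± 0.08), WRKY38, the salicylic acid synthesis gene EDS16 (0.55 ± 0.07) and its regulator CBP60G (0.55 ± 0.07). PR5, a pathogenesis-related protein, was at 2.04 ± 0.35, a call lost without WT replicate 1 (2.08). The list median was 0.93 (camera adjusted p = 3.89e-07), against an adjusted p of 0.37 with an estimated correlation. It was 0.92 with slide as a term, 0.89 within slide 1 and 0.50 within slide 2, and under median centring the list did not pass (1.03, camera adjusted p = 0.0671). The ethylene and JA co-regulated defence list rose by its median of 0.88 (camera adjusted p = 0.0146, and 0.988 with an estimated correlation), with ERF1 the 1 of 7 members that passed and 3 higher when adjusted over the list alone. Its median was 1.04 with slide as a term, 0.53 within slide 1 and 0.89 within slide 2, and without WT replicate 2 (0.53, camera adjusted p = 0.118) or under median centring (0.92, camera adjusted p = 0.768) it did not pass.

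In the oxylipin and xenobiotic detoxification list 7 of 10 members fell and 3 did not pass, with 1 higher and 7 lower when adjusted over the list alone. UGT74E2 and GSTU24 led it, followed by the alkenal reductase AER (−1.22 ± 0.12) and the cytochrome P450 CYP81D11 (−1.51 ± 0.17). Its median was −0.99 (camera adjusted p = 4.19e-06), against an adjusted p of 0.37 with an estimated correlation, and −1.06 with slide as a term, −0.79 within slide 1 and −1.20 within slide 2. Heat shock genes fell in 11 of 16 cases, 1 rose and 4 did not pass, with 1 higher and 12 lower when adjusted over the list alone. HSP17.6A stood at −1.18 ± 0.12, HSP18.2 at −1.02 ± 0.13 and the transcription factor DREB2A at −1.43 ± 0.17, and HSP21, which passed as lower, was not well above background after HW. The heat shock median was −1.04 (camera adjusted p = 2.14e-06), against an adjusted p of 0.988 with an estimated correlation, −0.97 with slide as a term, −1.26 within slide 1 and −0.53 within slide 2. Clock transcripts moved in the same arrays. CCA1, RVE1 and RVE8, which peak near dawn, were higher at 0.90 ± 0.06, 1.23 ± 0.10 and 0.77 ± 0.09, and ELF4, which peaks in the evening, was lower at −1.12 ± 0.12. Of the 14 clock genes 4 rose, 5 fell and 5 did not pass, with 4 higher and 6 lower when adjusted over the list alone, and the list did not pass (median −0.19, camera adjusted p = 0.64).

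Photosynthesis genes rose in 8 of 27 cases and 19 did not pass, against 19 higher when adjusted over the list alone, with a median of 0.40 (camera adjusted p = 4.19e-06), against an adjusted p of 0.988 with an estimated correlation. That median was 0.44 with slide as a term, 0.34 within slide 1 and 0.53 within slide 2. Of the abscisic acid and dehydration list 9 of 19 members fell and 10 did not pass, against 11 lower when adjusted over the list alone, with a median of −0.43 (camera adjusted p = 0.000272, and 0.988 with an estimated correlation). The abscisic acid and dehydration median was −0.42 with slide as a term and −0.58 within slide 1, and the list did not pass within slide 2 (−0.06, camera adjusted p = 0.433) or under median centring, where its median turned to 0.14 against 0.40 for all genes. Plastid and mitochondrial transcripts were higher by a median of 0.15 with 4 of 100 members past the threshold and 1 when adjusted over the list alone (camera adjusted p = 0.00346, and 0.988 with an estimated correlation). Their median was 0.19 with slide as a term, 0.12 within slide 1 and 0.17 within slide 2, and the list did not pass without WT replicate 2 (0.12, camera adjusted p = 0.0608) or under median centring (0.71, camera adjusted p = 0.771).

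Apart from ethylene and JA co-regulated defence, jasmonate lists did not pass in WT. JA biosynthesis had a median of 0.02 (camera adjusted p = 0.943), the list of JAZ repressors, MYC factors and JA catabolism −0.07 (camera adjusted p = 0.648), and JA and wound responsive defence 0.18 (camera adjusted p = 0.647). Medians of the indole and aliphatic glucosinolate lists were 0.06 (camera adjusted p = 0.806) and 0.18 (camera adjusted p = 0.104). For early wound, touch and elicitor responsive genes the median was −0.08 while the mean was 0.06 (camera adjusted p = 0.975), and for calcium signalling the median was 0.05. Tryptophan and camalexin (−0.22), reactive oxygen (−0.10), flavonoid and anthocyanin (0.07), volatile terpenoids and leaf volatiles (0.09), plasmodesmal callose (0.02), auxin responsive (0.17), cell wall loosening (0.02), senescence (0.23) and sugar starvation genes (0.10) also did not pass. Markers of guard cells (0.08), phloem (−0.02), xylem (0.04), epidermis and trichomes (−0.06) and root (0.44) did not pass, with camera adjusted p of at least 0.64, nor did the reference genes, at −0.04.

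With slide as a term 1816 genes passed in WT, while 242 passed within slide 1 and, by limma, 0 within slide 2, where WT had a single array and 2857 genes had an unadjusted p under 0.05. The count was 623 without WT replicate 1, of which 301 were higher and 322 lower, 999 without WT replicate 3 and 1516 without PDKO3 replicate 2, and under median centring 89% of calls were higher, against 55%.

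In PDKO3, medians of the heat shock, the abscisic acid and dehydration, and the phenylpropanoid and lignin lists were lower after HW than after MD, with 5 of 16, 7 of 19 and 6 of 17 members past the threshold, and none of them passed with an estimated correlation. Single genes such as EXL3 and XTH9 rose, and the salicylic acid pathway list did not pass. HSP90.1 (AT5G52640, probe on chromosome 5 from 21372227 to 21372286), a chaperone, fell 3.38-fold, at −1.76 ± 0.15 (n = 3, adjusted p = 0.00122). The chaperone HSP70 (AT3G12580) fell 2.77-fold, at −1.47 ± 0.14 (adjusted p = 0.00205). The jasmonate sulfotransferase ST2A (AT5G07010) fell 3.25-fold, at −1.70 ± 0.19 (adjusted p = 0.00325). EXL3 (AT5G51550), a phosphate-responsive family protein, rose 4.51-fold, at 2.17 ± 0.28 (adjusted p = 0.00504), a call lost without PDKO3 replicate 2 (2.25).

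HW and MD differed in PDKO3 for 1959 genes, or 10.1%, with 1110 higher and 849 lower, and 31 and 97 of these by at least 2-fold. Falls that held without any one array were those of the proline-rich protein gene AT2G16630 (−2.01 ± 0.22), the GDSL lipase gene AT5G55050 (−1.93 ± 0.15), the DnaJ gene AT1G71000 (−1.80 ± 0.20), the glutathione transferase ERD9 (−1.64 ± 0.13), the dehydrins COR47 (−1.39 ± 0.15) and ERD10 (−1.26 ± 0.13), and the lignin synthesis gene HCT (−0.92 ± 0.10). Rises were less stable. XTH9, a cell wall xyloglucan enzyme, at 1.84 ± 0.31, ORA59, an ethylene and jasmonate transcription factor, at 1.43 ± 0.23, and the superoxide dismutase FSD1 at 1.06 ± 0.17 passed. Their calls were lost without PDKO3 replicate 2 (1.78, 1.25 and 0.92) and without PDKO3 replicate 3 (1.64, 1.2 and 1.06). VSP2 and VSP1, jasmonate-induced storage proteins, were at 1.15 ± 0.28 and 1.13 ± 0.29, and both did not pass without any one PDKO3 array (0.85 to 1.41) or without WT replicate 2, nor with slide as a term (1.14 and 1.15). Of the 70 named genes that passed in PDKO3, 12 kept their calls without any one array and 52 with slide as a term.

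Heat shock genes fell in 5 of 16 cases in PDKO3 and 11 did not pass, with 7 above 0, and with 1 higher and 6 lower when adjusted over the list alone. Their median was −0.18 (camera adjusted p = 0.00308, and 0.83 with an estimated correlation). It was −0.25 with slide as a term, −0.35 within slide 1 and −0.02 within slide 2, where 8 of 16 lay above 0. In the abscisic acid and dehydration list 7 of 19 members fell and 12 did not pass, against 9 lower when adjusted over the list alone, with a median of −0.45 (camera adjusted p = 1.81e-05, and 0.83 with an estimated correlation). That median was −0.41 with slide as a term, −0.57 within slide 1 and −0.33 within slide 2. The phenylpropanoid and lignin list had 6 of 17 members lower and 11 not past the threshold, against 1 higher and 10 lower when adjusted over the list alone, and a median of −0.39 (camera adjusted p = 0.0001, and 0.291 with an estimated correlation). Its median was −0.38 with slide as a term, −0.25 within slide 1 and −0.39 within slide 2. Under median centring, where all genes had a median of 0.46, these medians were −0.23, 0.22 and 0.41, so those of the abscisic acid and dehydration list and the phenylpropanoid and lignin list turned above 0, and neither passed (camera adjusted p = 0.123 and 0.92).

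Of the JA biosynthesis list in PDKO3 1 of 16 members passed, AOC3 (−0.71 ± 0.10, lost without PDKO3 replicate 2, −0.70), and 3 were lower when adjusted over the list alone. The list median was −0.33 (camera adjusted p = 0.000203, and 0.83 with an estimated correlation). This median was −0.33 with slide as a term, −0.39 within slide 1 and −0.30 within slide 2. In the list of JAZ repressors, MYC factors and JA catabolism 3 of 19 members fell and 16 did not pass, with 3 lower when adjusted over the list alone, among them ST2A and the jasmonate oxidase CYP94C1 (−1.13 ± 0.14, lost without PDKO3 replicate 2, −1.11). That list had a median of −0.22 (camera adjusted p = 0.00124, and 0.83 with an estimated correlation). That value was −0.24 with slide as a term, −0.31 within slide 1 and −0.19 within slide 2. Under median centring neither of these lists passed and the medians turned to 0.57 and 0.41, against 0.46 for all genes. The ethylene and JA co-regulated defence list was higher by a median of 1.06 (camera adjusted p = 0.00816, and 0.83 with an estimated correlation), with ORA59 past the threshold among 7 members and 4 higher when adjusted over the list alone. Its median was 0.91 with slide as a term, 0.70 within slide 1 and 1.23 within slide 2, and the list did not pass without PDKO3 replicate 3 (0.26, camera adjusted p = 0.142) or under median centring (1.51, camera adjusted p = 0.445).

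Photosynthesis genes were higher by a median of 0.31 in PDKO3, with 5 of 27 past the threshold and 9 when adjusted over the list alone (camera adjusted p = 0.00102, and 0.83 with an estimated correlation). The list stood at 0.30 with slide as a term, 0.36 within slide 1 and 0.22 within slide 2. Cytosolic ribosomal proteins had a median of 0.12, with 17 of 177 members higher, 2 lower and 158 not past the threshold, and 23 and 2 when adjusted over the list alone (camera adjusted p = 0.00112, and 0.83 with an estimated correlation). The ribosomal median was 0.12 with slide as a term, 0.16 within slide 1 and 0.10 within slide 2. Detoxification, which fell in WT, had 2 of 10 members lower in PDKO3, 3 when adjusted over the list alone, and a median of −0.19 (camera adjusted p = 0.0259, and 0.83 with an estimated correlation). The oxylipin and xenobiotic detoxification median was −0.16 with slide as a term, −0.21 within slide 1 and −0.14 within slide 2, and the list did not pass without PDKO3 replicate 1 (−0.16, camera adjusted p = 0.125) or under median centring (0.10). Of 16 flavonoid and anthocyanin genes 6 rose, also when adjusted over the list alone, at a list median of 0.11 that did not pass (camera adjusted p = 0.189). The salicylic acid pathway list had a median of 0.07 (camera adjusted p = 0.819), and the 14 clock genes had a median of −0.04 (camera adjusted p = 0.954), with none of them past the threshold over all genes and 3 higher when adjusted over the list alone.

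With slide as a term 1332 genes passed in PDKO3, while 89 passed within slide 2 and, by limma, 0 within slide 1, where PDKO3 had a single array and 2632 genes had an unadjusted p under 0.05. The count was 1112 without PDKO3 replicate 1, 116 without PDKO3 replicate 2 and 261 without PDKO3 replicate 3. Without any one of these arrays most calls were falls (477 higher and 635 lower, 27 and 89, and 86 and 175), as within slide 2 (14 and 75), and with slide as a term they were 666 each. Under median centring 96% of calls were higher, against 57%.

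After MD alone, the median of the JA and wound responsive defence list was lower in PDKO3 than in WT, with 6 of 14 members past the threshold, a call lost without replicate 2 between genotypes and with an estimated correlation. That of the ethylene and JA co-regulated defence list was higher and did not pass, and the ethylene receptor genes ETR2, ERS1 and ERS2 were higher. VSP2 (AT5G24770, probe on chromosome 5 from 8500709 to 8500768), a storage protein induced by jasmonate, was 8.06-fold lower, at −3.01 ± 0.35 (n = 2, adjusted p = 0.00213), and VSP1 (AT5G24780) 7.17-fold lower, at −2.84 ± 0.36 (adjusted p = 0.00288). UGT74E2 was 7.37-fold lower, at −2.88 ± 0.18 (adjusted p = 0.000409). EBF2 (AT5G25350), an F-box protein of ethylene signalling, was 4.24-fold higher, at 2.09 ± 0.15 (adjusted p = 0.000446), and the ethylene receptor ETR2 (AT3G23150) 3.15-fold higher, at 1.66 ± 0.11 (adjusted p = 0.00042).

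Between genotypes 2729 of 19423 genes, or 14.1%, differed, 1344 higher and 1385 lower in PDKO3, and 157 and 254 of these by at least 2-fold. The highest rises that held without any one array were in AT5G57760 (3.29 ± 0.30), BT2 (2.62 ± 0.34), the cytokinin response regulator RR16 (2.55 ± 0.22) and the gibberellin methyltransferase GAMT2 (2.21 ± 0.20). Falls that held were in the defensin-like gene AT2G16367 (−3.29 ± 0.22), the myrosinase-binding protein MBP1 (−2.69 ± 0.28), the anthocyanin regulator PAP1 (AT1G56650, −2.39 ± 0.26), the cold response factor DREB1A (−2.10 ± 0.29), GSTU24 (−1.64 ± 0.12), the light-harvesting protein LHCB2.1 (−1.43 ± 0.17) and the catalase CAT2 (AT4G35090, −1.14 ± 0.10). ERF2 (1.57 ± 0.19), TCH3 (1.33 ± 0.17) and the jasmonate oxidase CYP94C1 (1.16 ± 0.17) were higher. CHAT, which makes a leaf volatile ester, at −2.17 ± 0.31, the ocimene synthase TPS10 (AT2G24210) at −2.05 ± 0.36 and the abscisic acid synthesis gene NCED3 at −1.13 ± 0.15 were lower, calls lost without replicate 2 between genotypes (−1.53, −1.49 and −1.02). AT1G53540 was lower at −2.84 ± 0.51, a call lost without either replicate (−2.59 and −3.10). Of the 104 named genes that passed, 38 kept their calls without any one array and 98 with slide as a term.

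Among JA and wound responsive defence genes 6 of 14 were lower in PDKO3 and 8 did not pass, with 2 higher and 7 lower when adjusted over the list alone. Their median was −0.71 (camera adjusted p = 0.0303, and 0.812 with an estimated correlation). Here the median was −0.71 with slide as a term, −0.52 within slide 1 and −0.98 within slide 2, and the list did not pass within slide 1 (camera adjusted p = 0.187) or without replicate 2 between genotypes (−0.52, camera adjusted p = 0.216). Other jasmonate lists did not pass between genotypes. JA biosynthesis had a median of 0.08, with 1 of 16 members higher (camera adjusted p = 0.543). JAZ repressors, MYC factors and JA catabolism had a median of −0.09, with 2 of 19 higher and 1 lower (camera adjusted p = 0.827). In the ethylene synthesis and perception list 5 of 15 members were higher and 10 did not pass, with 6 higher when adjusted over the list alone. Besides ETR2 and EBF2 these included the receptors ERS1 (2.29-fold) and ERS2 (2.12-fold). Its median was 0.21 (camera adjusted p = 0.0061, and 0.504 with an estimated correlation). The value was 0.21 with slide as a term, 0.24 within slide 1 and 0.18 within slide 2, and it did not pass under median centring (0.92, camera adjusted p = 0.0569). The salicylic acid pathway list was higher by a median of 0.57, with 3 of 17 past the threshold and 4 when adjusted over the list alone (camera adjusted p = 0.0236, and 0.504 with an estimated correlation). The salicylic acid median was 0.57 with slide as a term, 0.45 within slide 1 and 0.44 within slide 2, and the call was lost without replicate 1 between genotypes (0.44, camera adjusted p = 0.101).

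Medians of aliphatic glucosinolate synthesis and glucosinolate breakdown genes were lower in PDKO3. Of the aliphatic glucosinolate synthesis list 8 of 18 fell and 10 did not pass, against 14 lower when adjusted over the list alone, led by the regulator MYB29 (−1.16 ± 0.14). The median was −0.42 (camera adjusted p = 1.87e-06, and 0.504 with an estimated correlation). It was −0.42 with slide as a term, −0.28 within slide 1 and −0.47 within slide 2. For glucosinolate breakdown 3 of 11 fell and 8 did not pass, with 6 lower when adjusted over the list alone, at a median of −0.36 (camera adjusted p = 0.0259, and 0.504 with an estimated correlation). That median was −0.36 with slide as a term, −0.31 within slide 1 and −0.41 within slide 2. Under median centring both lists did not pass and their medians turned to 0.46 and 0.22, below the 0.55 of all genes. In the oxylipin and xenobiotic detoxification list 5 of 10 members were lower, 1 higher and 4 not past the threshold, also when adjusted over the list alone, at a median of −0.49 (camera adjusted p = 0.000902, and 0.504 with an estimated correlation). This median was −0.49 with slide as a term, −0.24 within slide 1 and −0.82 within slide 2. Heat shock genes were lower in 5 of 16 cases and higher in 1, with 6 and 1 when adjusted over the list alone, at a median of −0.43 (camera adjusted p = 0.0236, and 0.812 with an estimated correlation). The heat shock median was −0.43 with slide as a term and −0.75 within slide 1, and the list did not pass within slide 2 (−0.23, camera adjusted p = 0.0631) or without replicate 1 between genotypes (−0.23, camera adjusted p = 0.249).

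Clock transcripts differed between genotypes in the same samples. CCA1, at −1.32 ± 0.08, and RVE8, at −0.84 ± 0.11, were lower in PDKO3, and the evening genes ELF4, at 1.60 ± 0.14, and GRP7, at 1.27 ± 0.13, were higher. In the circadian clock list 6 of 14 members were higher, 3 lower and 5 not past the threshold, with 7 and 5 when adjusted over the list alone, and the list as a whole did not pass (median 0.14, camera adjusted p = 0.687).

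**Figure D2:**
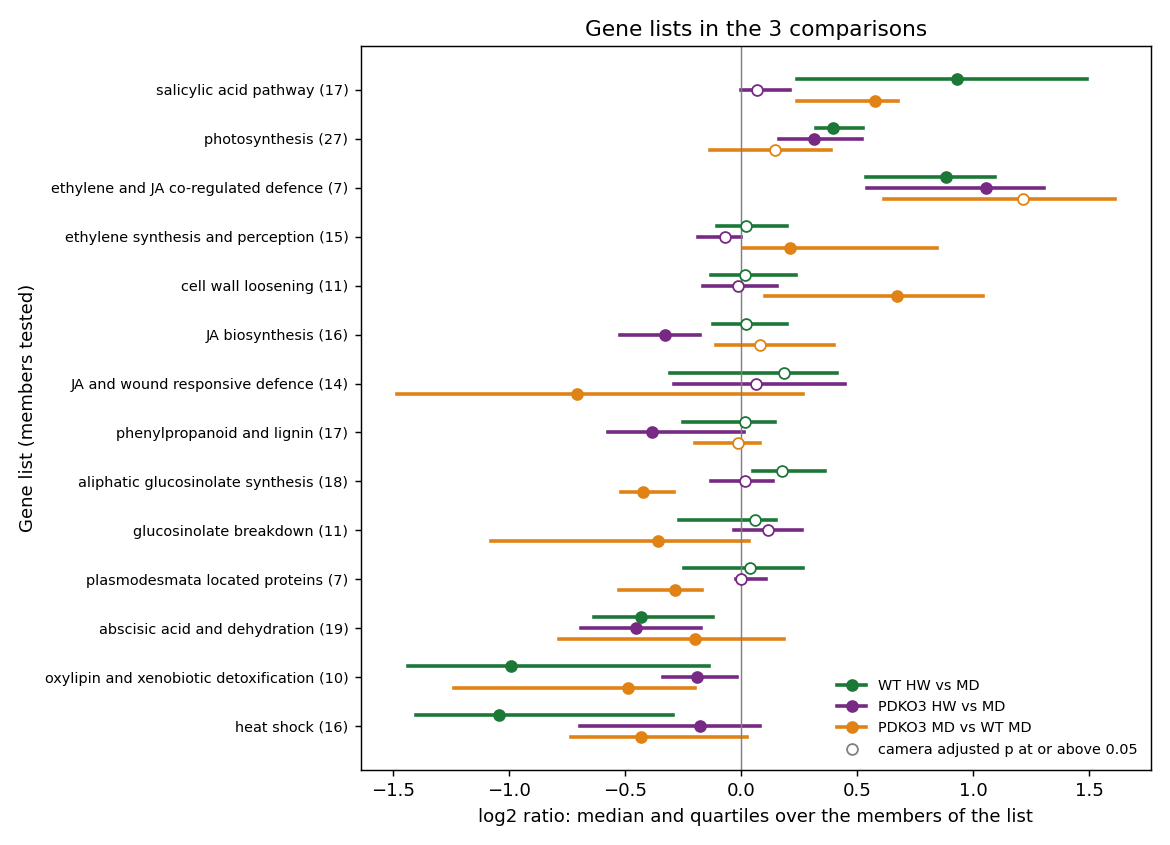
Medians (points) and quartiles (lines) of log2 ratios over the members of 14 gene lists in the 3 comparisons, with filled points for lists past the threshold at the preset correlation. The oxylipin and xenobiotic detoxification list had medians of −0.99, −0.19 and −0.49, and 0 lists passed with an estimated correlation (limma camera, 2, 1 and 2 lists with an unadjusted p under 0.05). Under median centring, which moved all genes up by 0.40 to 0.55, medians of abscisic acid and dehydration genes turned above 0 in each comparison, as did those of JA biosynthesis, phenylpropanoid and lignin, and detoxification genes in PDKO3 and of glucosinolate genes between genotypes.

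**Figure D3:**
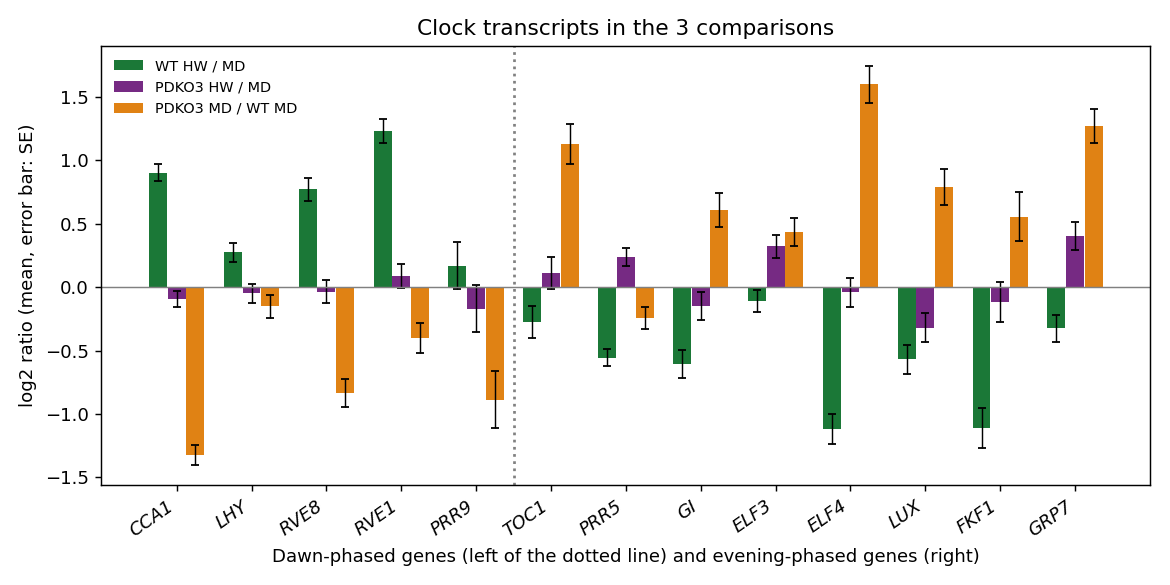
Log2 ratios of clock transcripts with SE in the 3 comparisons, with genes that peak near dawn on the left and evening genes on the right. CCA1 stood at 0.90 in WT HW against MD and at −1.32 in PDKO3 MD against WT MD.

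Further lists passed between genotypes. Cell wall loosening genes were higher by a median of 0.67, with 3 of 11 past the threshold, also when adjusted over the list alone, among them XTH4 (1.89 ± 0.27) and, measured on 1 of 2 arrays, the expansin EXPA8 (1.85 ± 0.31). The list's camera adjusted p was 0.0393, and 0.504 with an estimated correlation, and its median was 0.67 with slide as a term, 0.26 within slide 1 and 0.73 within slide 2, not past the threshold without replicate 2 between genotypes (0.26, camera adjusted p = 0.221). Senescence genes were higher by a median of 0.62, with 3 of 6 past the threshold and 4 when adjusted over the list alone (camera adjusted p = 0.0433, and 0.504 with an estimated correlation). Their median was 0.62 with slide as a term and 0.59 within slide 1, and the senescence list did not pass within slide 2 (0.68, camera adjusted p = 0.193) or without replicate 1 between genotypes (0.68, camera adjusted p = 0.339). Plasmodesmal callose genes were higher by a median of 0.30, with 3 of 12 past the threshold and 5 when adjusted over the list alone (camera adjusted p = 0.0441, and 0.722 with an estimated correlation). The plasmodesmal callose median was 0.30 with slide as a term and 0.45 within slide 2, and the list did not pass within slide 1 (0.05, camera adjusted p = 0.485) or without replicate 2 between genotypes (0.05, camera adjusted p = 0.656).

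Abscisic acid and dehydration genes were lower by a median of −0.20, with 5 of 19 lower and 1 higher, and 7 and 2 when adjusted over the list alone (camera adjusted p = 0.0303, and 0.815 with an estimated correlation). HAB1 (−1.06 ± 0.14) and ABF3 (−0.91 ± 0.11), a phosphatase and a transcription factor of abscisic acid signalling, were among them. The abscisic acid and dehydration median was −0.20 with slide as a term and −0.42 within slide 2, and the list did not pass within slide 1 (−0.06, camera adjusted p = 0.516), without replicate 2 between genotypes (−0.06, camera adjusted p = 0.584) or under median centring (0.54). Cytosolic ribosomal proteins, with 11 of 177 lower and 4 higher, and 9 and 2 when adjusted over the list alone, had a median of −0.05 (camera adjusted p = 0.0433, and 0.841 with an estimated correlation). The cytosolic ribosomal proteins had a median of −0.05 with slide as a term and −0.15 within slide 1, but 0.06 within slide 2, 0.06 without replicate 1 between genotypes and 0.71 under median centring, where their direction turned. Under median centring the senescence (1.3), cell wall loosening (1.43), plasmodesmal callose (1.06) and salicylic acid (1.18) lists did not pass either, with camera adjusted p of 0.307, 0.417, 0.213 and 0.699. The ethylene and JA co-regulated defence list, at a median of 1.21 with 6 of 7 members above 0, did not pass (camera adjusted p = 0.0945). Over all genes 1 of its members passed, as lower, and 6 did not pass, while 6 were higher and 1 lower when adjusted over the list alone. Nor did guard cell markers (3 of 6 higher, median 0.23, camera adjusted p = 0.391) or reference genes (2 of 11 higher, median 0.02, camera adjusted p = 0.733) pass.

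With slide as a term 2323 genes passed between genotypes, while 1165 passed within slide 2 and, by limma, 0 within slide 1, where 3094 genes had an unadjusted p under 0.05. The count was 1346 without replicate 1 between genotypes and 721 without replicate 2, and under median centring 90% of calls were higher, against 49%.

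A further test asked which HW against MD ratios differed between PDKO3 and WT, and it removes any dye effect shared by the arrays. The median ratio of the detoxification list was higher in PDKO3, with 3 of 10 members past the threshold, and that of the salicylic acid pathway list lower, with 2 of 17, and neither list passed with an estimated correlation. Of the dawn clock genes CCA1, RVE1 and RVE8 had a lower ratio, LHY and PRR9 did not pass, and nor did the clock list. UGT74E2 differed by 2.81 ± 0.20 (n = 3 and 3, adjusted p = 0.00294), GSTU24 by 2.01 ± 0.14 (adjusted p = 0.00294) and GSTU1 (AT2G29490) by 1.99 ± 0.15 (adjusted p = 0.00294). The iron-sulfur protein NEET (AT5G51720) differed by 1.83 ± 0.15 (adjusted p = 0.00294), and CCA1 (AT2G46830, probe on chromosome 2 from 19255709 to 19255768) by −0.99 ± 0.09 (adjusted p = 0.00375).

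In all, 353 genes, or 1.82%, had a different ratio, 187 higher and 166 lower in PDKO3, and 51 and 70 of these by at least 2-fold. The genes of the preceding values held without any one array, as did 7 of the 38 named genes that passed, and 29 of the 38 passed with slide as a term. Of the 353 genes, 272 had the opposite sign in PDKO3 MD against WT MD. That comparison shares MD samples with the difference, so part of this may come from them. Only 67 of the 353 were also called in the derived contrast of PDKO3 against WT after HW. WRKY38 differed by −2.59 ± 0.44 and NIA1 by −1.76 ± 0.26, calls lost without WT replicate 1 (−2.55 and −1.74) and without each PDKO3 array (−2.51 to −2.69 and −1.61 to −1.94). WRKY62 differed by −0.90 ± 0.11, CYP94C1 by −1.17 ± 0.19 and TCH3 by −1.19 ± 0.20, calls lost without each PDKO3 array (−0.88 to −0.93, −1.08 to −1.28 and −1.12 to −1.25). The heat shock genes did not move alike. HSP70 (−1.65 ± 0.20) and HSP90.1 (−1.37 ± 0.21) had a lower ratio in PDKO3, and HSP18.2 (1.14 ± 0.18) and HSP17.6A (1.08 ± 0.18) a higher one. HSP70 was lost without PDKO3 replicate 1 (−1.53) or 2 (−1.66), and HSP90.1 without any one PDKO3 array (−1.22, −1.45 and −1.44) or WT replicate 1 (−1.21). The small heat shock protein genes were lost without any one PDKO3 array (1.12 to 1.18 for HSP18.2 and 1.05 to 1.13 for HSP17.6A), WT replicate 1 (1.00 and 1.02) or WT replicate 3 (1.1 and 1.00).

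Of the salicylic acid pathway list 2 of 17 members had a lower ratio in PDKO3 and 15 did not pass, against 12 lower when adjusted over the list alone, at a median difference of −0.75 (camera adjusted p = 2.86e-07, and 0.341 with an estimated correlation). That median was −0.68 with slide as a term, −0.89 within slide 1 and −0.45 within slide 2. The oxylipin and xenobiotic detoxification list had 3 of 10 members with a higher ratio, and 6 higher and 1 lower when adjusted over the list alone, at a median of 0.49 (camera adjusted p = 0.000461, and 0.48 with an estimated correlation). Its median was 0.59 with slide as a term, 0.36 within slide 1 and 0.69 within slide 2. In the phenylpropanoid and lignin list, 4 of 17 members had a lower ratio when adjusted over the list alone and none over all genes, at a median of −0.25 (camera adjusted p = 0.000101, and 0.291 with an estimated correlation). That value was −0.19 with slide as a term, −0.33 within slide 1 and −0.22 within slide 2. JA biosynthesis had 1 of 16 members with a lower ratio and 4 when adjusted over the list alone, at a median of −0.33 (camera adjusted p = 0.00124, and 0.786 with an estimated correlation). The list stood at −0.34 with slide as a term, −0.23 within slide 1 and −0.46 within slide 2. Cytosolic ribosomal proteins had a median of 0.14, although the 1 of 177 members that passed was lower (camera adjusted p = 0.000228, and 0.786 with an estimated correlation). Here the median was 0.14 with slide as a term, 0.15 within slide 1 and 0.17 within slide 2.

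A further 5 lists passed the test of the difference and depended on single arrays. Heat shock genes had a median of 0.70 (camera adjusted p = 0.0453, and 0.786 with an estimated correlation), with 4 of 16 higher and 2 lower, and 9 and 4 when adjusted over the list alone. The heat shock median was 0.55 with slide as a term, 0.73 within slide 1 and 0.25 within slide 2 (camera adjusted p = 0.382). That call was lost without PDKO3 replicate 1 (0.62) or 3 (0.67), WT replicate 1 (0.64) or 3 (0.51), or either array between genotypes (0.70). The auxin responsive list, in which no member passed alone, had a median of −0.49 (camera adjusted p = 0.0334, and 0.786 with an estimated correlation). The value was −0.57 with slide as a term, −0.46 within slide 1 and −0.66 within slide 2, lost without WT replicate 2 (−0.37) or 3 (−0.26). Aliphatic glucosinolate synthesis, also with no member past the threshold, had a median of −0.18 (camera adjusted p = 0.0334, and 0.786 with an estimated correlation). It was −0.19 with slide as a term, −0.05 within slide 1 and −0.32 within slide 2, lost without WT replicate 1 (−0.15) or 2 (−0.08). Calcium signalling, with 1 of 22 members lower and 3 when adjusted over the list alone, had a median of −0.12 (camera adjusted p = 0.0453, and 0.48 with an estimated correlation). This median was −0.06 with slide as a term, −0.15 within slide 1 and 0.03 within slide 2, lost without PDKO3 replicate 2 (−0.02) or WT replicate 1 (−0.05). JAZ repressors, MYC factors and JA catabolism, with 1 of 19 members lower and 2 when adjusted over the list alone, had a median of −0.26 (camera adjusted p = 0.0453, and 0.786 with an estimated correlation). That value was −0.28 with slide as a term, −0.21 within slide 1 and −0.53 within slide 2. Without PDKO3 replicate 1 (−0.17) or 2 (−0.22) or WT replicate 1 (−0.10) or 2 (−0.07) this call was lost. Under median centring the heat shock (0.69), calcium (−0.06) and JAZ (−0.12) lists did not pass, with camera adjusted p of 0.127, 0.0536 and 0.0536. Clock genes, with 2 higher, 3 lower and 9 not past the threshold, had a median of 0.32 that did not pass (camera adjusted p = 0.491).

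With slide as a term 212 genes had a different ratio, and by limma 0 did within either slide, where 1729 and 2229 genes had an unadjusted p under 0.05. The count was 61, 22 and 36 without PDKO3 replicates 1, 2 and 3 and 87 without WT replicate 1. Without any one of the 6 HW arrays most of these had a lower ratio, with 36% to 47% higher, against 53%.

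Over both genotypes, the mean HW against MD ratio on 6 arrays differed from 0 for 4585 genes, with 2718 higher and 1867 lower and 35 and 48 of these by at least 2-fold. Photosynthesis genes rose in 19 of 27 cases, with a median of 0.30 (camera adjusted p = 6.54e-06, and 0.771 with an estimated correlation). The list stood at 0.30 with slide as a term, 0.37 within slide 1 and 0.37 within slide 2. In the ethylene and JA co-regulated defence list 5 of 7 members rose, with a median of 0.84 (camera adjusted p = 0.00401, and 0.771 with an estimated correlation). Here the median was 0.84 with slide as a term, 0.86 within slide 1 and 0.92 within slide 2, and it did not pass under median centring (1.17, camera adjusted p = 0.579). Heat shock genes fell in 13 of 16 cases and rose in 2, with a median of −0.65 (camera adjusted p = 3.38e-07, and 0.771 with an estimated correlation). The value was −0.65 with slide as a term, −0.82 within slide 1 and −0.38 within slide 2. Abscisic acid and dehydration genes fell in 10 of 19 cases, with a median of −0.45 (camera adjusted p = 6.54e-06, and 0.771 with an estimated correlation). It was −0.45 with slide as a term, −0.56 within slide 1, −0.30 within slide 2 and 0.22 under median centring, where they did not pass.

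Calls over both genotypes numbered 4134 with slide as a term and 270 within slide 2, of which 99 were higher, and by limma 0 within slide 1, where 4691 genes had an unadjusted p under 0.05. Without PDKO3 replicate 2 or 3 or WT replicate 1 there were 1757, 2389 and 2673 calls, and under median centring 89% of calls were higher, against 59%.

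The calls in WT and PDKO3 overlapped. Both genotypes shared 230 rises, where independent lists of these sizes would share 76.6, and 324 falls, against 48.5, while 10 genes rose in WT and fell in PDKO3 and 30 did the opposite. HW calls in WT and calls between genotypes shared 262 rises and 333 falls, against 92.7 and 79.2. In opposite directions, 73 genes rose in WT and were lower in PDKO3, and 80 fell in WT and were higher in PDKO3, against 95.5 and 76.8. These comparisons share WT MD samples, and simulated unchanged groups gave a correlation of 0.412 across genes, against 0.340 observed. The covariance was 0.0364 against 0.00638 simulated, a difference of 0.0300. For PDKO3 HW against MD and the comparison between genotypes the correlation was −0.0453, against −0.409 simulated, with covariances of −0.00432 and −0.00632. For the difference between genotypes it was −0.376, against −0.581 simulated, with covariances of −0.0407 and −0.0127. The simulated groups shared MD RNA between arrays of the same replicate number, which the labels do not state. All of the simulated spread lay in the RNA and none in the hybridisation, so the simulated values are at the upper end of what shared RNA gives. Replicate 2 between genotypes correlated at 0.485 with WT replicate 3 and at 0.284 with WT replicate 2. For replicate 1 between genotypes r was 0.226 with WT replicate 3 and 0.196 with WT replicate 1. The replicate numbers may therefore not name the arrays that share RNA. In 20 simulations at most 1 gene was called in a comparison, and none in both. The simulations therefore cannot show how many shared calls come from shared controls. The controls could not be split, so part of each excess with the comparison between genotypes may come from the shared controls. Without a dye swap, a constant dye effect may also add calls in the same direction. This holds for the overlap of WT with PDKO3 and for that of WT with the comparison between genotypes.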

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

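The results in this part were singled out because the HW against MD ratio differed between PDKO3 and WT by a test of the difference itself. The tests of dye, single arrays, slide and steady drift, and their limits, were chosen after the results were seen, those of steady drift after 4 criteria had been compared on their values, of which 2 were kept and then required without each array before those values were seen. The test of harvest time was chosen after the clock shift was seen, with its second set of transcripts and its prediction written before their values were seen, and only the tests of other splits were set before.

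In total 353 genes and 10 gene lists had a different ratio. The 6 HW arrays can be split in 10 ways, the real one included, which is too few for a share under 0.05. The real split gave 353 genes, and the highest other split 0 (limma, with 3296 genes at an unadjusted p under 0.05 in the real split), so that 1 split of 10 reached the real count. For lists the real split gave 10 and the highest other 19, and 4 splits of 10 reached the real count. The list medians were −0.33 for JA biosynthesis, −0.26 for JAZ repressors, MYC factors and JA catabolism, −0.75 for the salicylic acid pathway, −0.18 for aliphatic glucosinolate synthesis, −0.12 for calcium signalling, 0.49 for oxylipin and xenobiotic detoxification, 0.70 for heat shock, −0.25 for phenylpropanoid and lignin, −0.49 for auxin responsive and 0.14 for cytosolic ribosomal proteins.

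Genes with a higher ratio in PDKO3 were UGT74E2 (2.81), LTP3 (2.11), AT5G16980 (2.03), GSTU24 (2.01), GSTU1 (1.99), NEET (1.83), AT2G37870 (1.79), UGT75B1 (1.78), AT3G62550 (1.76), DOGT1 (1.71), CYP81D11 (1.70), HSP18.2 (1.14), HSP17.6A (1.08), ELF4 (1.08) and PRR5 (0.79). Genes with a lower ratio were WRKY38 (−2.59), AT1G13470 (−2.34), CRK6 (−2.11), HR4 (−1.82), NIA1 (−1.76), QQS (−1.73), Hsp70-2 (−1.71), AT3G57460 (−1.69), RLP34 (−1.68), AT5G10760 (−1.66), HSP70 (−1.65), HSP90.1 (−1.37), TCH3 (−1.19), CYP94C1 (−1.17), CYP82G1 (−1.16), RVE1 (−1.15), FLS1 (−1.07), CCA1 (−0.99), AOC3 (−0.95), WRKY62 (−0.90), TT4 (−0.73), ETR2 (−0.64) and the ribosomal protein gene AT3G04230 (−0.48).

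Dawn clock transcripts lay above evening ones in WT HW against MD by 1.33 and below them in PDKO3 MD against WT MD by −1.54. A constant dye effect would give the PDKO3 HW arrays the same value as the WT ones, and the highest PDKO3 array lay at 0.0948 while the lowest WT array lay at 1.14, which also argues against 1 array as the source. Had samples been harvested at different times, 12 clock transcripts outside the first list would part in the same way. They did, by 0.82 in WT and by −1.32 between genotypes (exact permutation across genes of the same arrays, p = 0.0141 and 0.0162, which measures no spread between plants). A harvest time difference, or a biological effect of treatment and genotype on the clock, may therefore underlie the pattern, and the labels give no harvest times that could part these.

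Medians of detoxification and heat shock transcripts were lower in WT HW and in PDKO3 MD than in WT MD, and on leaving out each WT array those nearest to 0 were −0.79 and −0.88, both past the threshold, with no array nearer to 0 than −0.69 and −0.53 (SD 0.25 and 0.42), which argues against 1 array for the fall in WT. Between genotypes, where 5 of 10 and 5 of 16 members were lower and the medians without 1 of the 2 arrays reached −0.24 and −0.23 (SD of the arrays 0.41 and 0.36), the latter not past the threshold, 1 array cannot be told apart from the whole group. The nearest WT and PDKO3 arrays were 0.48 apart for detoxification, which argues against a constant dye effect there as the whole cause, and 0.19 for heat shock, less than the SD, so that a dye effect stays open there, while 4 members passed with a higher and 2 with a lower ratio in PDKO3. A steady drift with harvest time like that of the clock, as the whole cause, needs PDKO3 HW above WT HW by at least the fall in WT (0.99 and 1.04), and the derived medians were −0.0542 and 0.24, so that for detoxification, short by 1.05 against an SD of 0.30 over members (interquartile range 0.26, but 1.3 in WT) and by more than both derived spreads without each of 8 arrays, the values argue against it, while for heat shock, at 1 of 8, it stays open. The spreads over members are taken across genes of the same arrays and measure no spread between plants. Shared WT MD RNA stays open too, as does an effect of genotype or treatment, untested on independent plants.

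The median of salicylic acid transcripts was higher after HW in WT, with 11 of 17 past the threshold, and the list did not pass with an estimated correlation (camera adjusted p = 0.37) or under median centring (0.0671). At the preset correlation, on leaving out each WT array the list median nearest to 0 was 0.70, past the threshold, with no array nearer to 0 than 0.50 (SD 0.21), which argues against 1 array. Within slide 2 the difference between genotypes had a median of −0.45 with quartiles of −0.55 and −0.17, and within slide 1 one of −0.89 with quartiles of −2.06 and −0.29, which argues against slide. A steady drift as the whole cause needs a derived median of −0.93 or lower, and it was −0.24, short by 0.69 against an interquartile range of 0.66 (1.25 in WT), but by more than both derived spreads without only 3 of 8 arrays, so that drift stays open, and the 0.57 in PDKO3 MD against WT MD shares WT MD samples. An effect of genotype on the response to feeding stays open, untested on independent plants, as does shared WT MD RNA.

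Sign flips of the arrays were counted for the other tests. In WT 1 of 4 flips reached the real count of 2450 genes (highest other 0) and 3 of 4 that of 7 lists (highest other 12). In PDKO3 these were 1 of 4 for 1959 genes (highest other 0) and 2 of 4 for 9 lists (highest other 18). With 4 flips no share under 0.05 is possible, and by limma 5870 and 5375 genes had an unadjusted p under 0.05 in the real grouping. Over both genotypes 1 of 32 flips, the real grouping, reached 4585 genes. That is the smallest share that 32 flips can give, and it argues against chance alone without excluding it. The highest other flip, 353, equals the count for the difference between genotypes. HW carried Cy5 on each of these arrays, so a constant dye effect would give the same outcome. For lists 13 of 32 flips reached 10 (highest other 18), so chance is not excluded there.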

How the results depend on the processing

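The fits within each slide and the median values of lists under each setting were chosen after seeing the data, and the other alternatives were set before. The number of arrays and probes near background limit the calls, and a single array left in a set is assumed to vary like the others.

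Counts of genes that moved by over 1.5 times are given against the reported 2450 in WT, 1959 in PDKO3, 2729 between genotypes, 353 for the difference and 4585 over both genotypes. Median centring gave 12593, 12286, 13119, 107 and 15281, with 89%, 96%, 90%, 51% and 89% of calls higher, against 55%, 57%, 49%, 53% and 59%, which for the single comparisons and the mean follows from the shift of all genes by 0.40 to 0.55, while for the difference the cause was not tested. Scaling between arrays gave 1593 in WT, 3169 in PDKO3 and 1048 between genotypes, the scanner log ratio 1518 in WT, no background subtraction 3921 in PDKO3 and 583 for the difference, and an offset of 0 gave 769 and 149 there. With only the arrays of a comparison, where the spread rests on fewer arrays, there were 654 in WT, 3120 in PDKO3 and by limma 0 between genotypes (4410 genes at an unadjusted p under 0.05). The series table gave 3805 in PDKO3 and 638 for the difference, array weights 5364 and 1162, and separate channels 4181 in WT, 3456 in PDKO3, 5916 between genotypes and 1470 for the difference. For the other settings, apart from fewer arrays, the cause was not tested. At least 2-fold were 233, 128, 411, 121 and 83 genes.

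With slide as a term the difference had 212 genes. Within slide 1 there were 242 genes in WT and by limma 0 in PDKO3, 0 between genotypes, 0 for the difference and 0 over both (2632, 3094, 1729 and 4691 at an unadjusted p under 0.05), and within slide 2 by limma 0 in WT (2857), 89 in PDKO3, 1165 between genotypes, 0 for the difference (2229) and 270 over both, with fewer arrays in each fit. Scan and slide divided the arrays alike, so scan was not run separately.

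Leaving out each array gave 623 to 2612 genes in WT, 116 to 2376 in PDKO3, 721 to 3080 between genotypes, 22 to 495 for the difference and 1757 to 4825 over both. Lists past the threshold numbered 5 to 11, 9 to 10, 11 to 15, 7 to 13 and 8 to 10, against 7, 9, 13, 10 and 10. With an estimated correlation they were by camera 0 in WT, 0 in PDKO3, 0 between genotypes, 0 for the difference and 0 over both (2, 1, 2, 3 and 2 lists at an unadjusted p under 0.05), and under median centring 4 in PDKO3, 7 between genotypes and 5 over both.

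The groups share replicate numbers, and the replicate block gave 1876, 1503, 1875, 177 and 4017 genes. Deviations of WT and PDKO3 arrays with the same number correlated across genes with r of −0.02, −0.17 and −0.31, and none of them correlated best with the array of its own number. These values gave no sign that the numbers pair these arrays. With so few arrays, and deviations taken from the mean of each genotype, a link by number cannot be excluded. The arrays between genotypes were not in this check. Under the block 59 of 306 named calls were lost, as were those of plasmodesmal callose (0.31, camera adjusted p = 0.0781) and cytosolic ribosomal proteins (−0.04, camera adjusted p = 0.113) between genotypes and that of JAZ repressors, MYC factors and JA catabolism for the difference (camera adjusted p = 0.0641). With the values of the series abscisic acid and dehydration did not pass between genotypes (−0.22, camera adjusted p = 0.0657).

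Values that turned did so under median centring, except where stated. As mean shifts against other genes these were JA biosynthesis in PDKO3 (0.0460) and over both genotypes (0.19), phenylpropanoid and lignin over both genotypes (0.0299), and cytosolic ribosomal proteins between genotypes (0.17 under centring and 0.0137 within slide 2, with a range of −0.15 to 0.0137 on leaving out each array, the highest without replicate 1 between genotypes). Genes in WT were MYB29 (0.00762), AT2G04400 (0.17), ERD10 (0.22) and KCS10 (0.00821). In PDKO3 they were CYP94B3 (0.12), GSTF10 (0.63), SOT17 (0.50), ERF4 (0.24), APX1 (0.66), AOX1A (0.17), OPR1 (0.49), FAH1 (0.15), C4H (0.30), CCR1 (0.41), GSL8 (0.41), XTH18 (0.11), KCS10 (0.13) and ATCG00540 (0.69). Between genotypes they were MYC4 (0.14), IMD1 (0.32), AT2G31790 (0.47), SOT17 (0.45), LHCB2.2 (0.24), TT4 (0.0168), CCR1 (0.51), CLA1 (0.0200), PDLP1 (0.0635), APL (0.00797), AT3G13580 (0.21), AT3G53430 (0.45) and ATMG01370 (0.0894). Beyond the shift of all genes, the cause was not tested.

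Of the 306 named calls, all kept their sign under every other setting. For the largest rises and falls the naming rule fixed this in part, as it asked for the same sign on every array. Members of lists were named by their p in the same data, so the kept signs are no independent support. Median centring ended 51, only the arrays of the comparison 146, scaling 75, the scanner log ratio 65, an offset of 0 61, slide as a term 50, no filter 35, the mean of all probes 27, the values of the series 14, no background subtraction 11, array weights 9, the trended prior 8 and slide as a random block 3. Separate channels ended 5 of 296, the filter on all 8 arrays 1 of 304, the fit within slide 1 273 of 305 and that within slide 2 226.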

Other observations

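The comparison of PDKO3 with WT after HW and the clock sets were chosen after the results were seen, and the gene lists were set before.

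TT4, the chalcone synthase of flavonoid synthesis, rose by 0.79 ± 0.10 in WT after HW (adjusted p = 0.00387), and CYP82G1, which makes a volatile homoterpene, by 0.86 ± 0.10 (adjusted p = 0.00315). The calmodulin CAM9 rose by 1.01 ± 0.11 (adjusted p = 0.00214). The catalase gene CAT1 fell, at −0.74 ± 0.09. These calls held without any one array, and the ratios of TT4 (−0.73) and CYP82G1 (−1.16) were lower in PDKO3.

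PDKO3 HW and WT HW were never on the same array, and their contrast was derived from the 3 sets. By it 256 genes differed, 116 higher and 140 lower in PDKO3, and the medians were 1.72 for ethylene and JA co-regulated defence, −0.92 for JA and wound responsive defence, −0.24 for the salicylic acid pathway, 0.24 for heat shock and −0.05 for oxylipin and xenobiotic detoxification. In that order 0 of 7, 1 of 14, 0 of 17, 1 of 16 and 0 of 10 members were called by limma, all as lower. Quartiles of the first list were 0.27 and 2.05, and those of the second −1.72 and 0.12. The lists were not tested in this contrast, and a constant dye effect stays in it. Dawn minus evening clock transcripts stood at −2.84 in this contrast.

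Median, mean and camera direction differed in sign for some lists, none of which passed in that comparison. In WT these were glucosinolate breakdown, early wound, touch and elicitor responsive, phenylpropanoid and lignin, cell wall loosening, reference genes and cytosolic ribosomal proteins. In PDKO3 they were aliphatic glucosinolate synthesis, tryptophan and camalexin, reactive oxygen, volatile terpenoids, plasmodesmal callose, circadian clock, cell wall loosening, senescence and root markers. Between genotypes they were the JAZ and flavonoid lists, and for the difference JA and wound responsive defence, ethylene and JA co-regulated defence (median 0.30, mean 0.14, camera down), plasmodesmal callose and phloem markers. Over both genotypes they were ethylene synthesis and perception, indole glucosinolate synthesis, glucosinolate breakdown, calcium signalling, reactive oxygen, volatile terpenoids, plasmodesmal callose, auxin responsive, circadian clock, cell wall loosening, phloem and root markers.

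Other probes of a gene disagreed in sign for ETR1 in WT (0 of 2 other probes shared it), MYC4 between genotypes (0 of 1), LHCA1 in PDKO3 (3 of 4 shared it) and ATMG00020 between genotypes (1 of 2).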
